A study of Mus musculus with 23 samples.

How the data were processed

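The series profiles CD8+ T cells of NOD mice, a strain that develops autoimmune diabetes spontaneously. Mice whose CD8+ T cells carry a Cre-mediated deletion of floxed Lag3 are set against floxed mice without Cre, called control here. CD8+ T cells were sorted from pancreatic islets, from the pancreatic lymph node and from a non-draining lymph node. Of the 23 samples in the series, 17 were used: 16 bulk RNA libraries and 1 table of T cell receptor contigs. The other single-cell and multiome samples were not analysed here, and 2 of them were put in no group because their title and source labels name different tissues. The labels disagree on age, giving 8 weeks with each sample and in the design text and 30 weeks in the growth protocol. Per the design text, cells of 3 mice per group were pooled across 2 independent experiments for bulk RNA, and 4 mice per group went into single-cell libraries. The text does not tie single mice to libraries, so p-values measure the spread between these libraries, which may be partly technical.

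Per the labels' protocols, islets were released by collagenase in the duct for 30 min at 37 °C, picked by hand and dissociated for 15 min at 37 °C before sorting. The protocols describe no such digestion for lymph nodes. Bulk libraries were made with Smart-seq2, a full-length method without unique molecular identifiers, so values that rest on reads do not give the number of molecules. Standard errors cover counting error and the spread between libraries, while floors and intervals cover counting error alone. Single-cell libraries were made with a 10x Genomics 5′ kit. Submitters' processing notes name bcl2fastq 2.20.0, STAR 2.5.2a, limma without a version, Cell Ranger 3.1.0 and Cell Ranger ARC 2.0.0, with the build GRCm38, also called mm10. The program that counted reads per gene is not given in the sources used here, and neither is its strand setting.

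The bulk values deposited by the authors are whole-number counts of reads per gene for 25618 genes, with Ensembl gene IDs, symbols and coordinates. Library totals ran from 25972104 to 26054774, a ratio of 1.00, so the counts had been brought to a common depth by a step that the sources used here do not describe. If counts had simply been multiplied by a factor below 1 and rounded, neighbouring values would merge at regular steps and pile up among the low values. Factors above 1 were not tried. The strength of such a comb pattern was 4.22 to 7.12 in the real libraries, against 11.1 when the same counts were multiplied by 0.95 and 70.1 when multiplied by 0.8. Equal totals hide the original depth, so the precision of each library may differ from what its total implies. The T cell receptor table deposited by the authors gives reads and unique molecular identifier counts per assembled contig, with a clonotype for most cell barcodes and no genotype, tissue or mouse.

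Libraries were grouped from the labels into 6 groups, with 4 islet libraries and 2 libraries from each lymph node per genotype. Library numbers 1 and 5 are non-draining lymph node, 2 and 6 pancreatic lymph node, and 3, 4, 7 and 8 islets. The file headers carry a prefix ending in 11 for numbers 1 to 4 and in 9 for numbers 5 to 8. These are called run 11 and run 9 here, although what the prefix marks is not given in the sources used here. Both genotypes and all 3 tissues are present in each run.

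Main tests used edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. All 16 libraries entered 1 model of group means, with TMM scaling and a robust quasi-likelihood fit, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, leaving 16086 genes. The common dispersion was 0.609. Each of 11 contrasts was tested with glmQLFTest and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Adjusted p-values in the text are from edgeR unless another tool is named. CPM means a count scaled by the TMM-adjusted library total, and group values are mean ± SD over libraries. A fold against a group with 0 counts in every library is given as a lower bound from a floor of 3 counts per library. Such a bound, written as at least, covers counting error in those libraries and not the spread between libraries. For 20 symbols, more than 1 gene ID carries the name.

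A set of 25 gene lists was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Lists of T cell programs covered exhaustion, stem-like cells, naive and central memory cells, cytotoxic effectors, NK receptors, T cell receptor activation, tissue residency, proliferation, interferon response, glycolysis and hypoxia, oxidative phosphorylation, chemokine receptors, cytokine receptors and ribosomal proteins. Marker lists covered CD8 T cells, CD4 and regulatory T cells, B cells, myeloid cells, MHC class II, NK and gamma-delta T cells, islet endocrine cells, acinar cells, endothelial and stromal cells, erythroid cells and mitochondrially encoded genes. Lag3 was left out of every list, and some genes belong to more than 1 list. The test was repeated with a correlation estimated from the data and with fry. Counts of list members past the threshold are also given adjusted over the list alone.

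Groups, contrasts, tests, lists and the rule for named genes were fixed before the data were examined. For each contrast the rule names Lag3 and then the called genes with a mean CPM of at least 5 whose groups do not overlap, up to 10 in each direction, or 5 for lymph node contrasts and interactions. Predicted genes and receptor segments are left out. It adds up to 4 members per list by smallest adjusted p, and where few genes pass it gives up to 5 with the smallest unadjusted p as not passing. Cd8a, Cd8b1, Cd4 and Cd3e are named as identity checks. A few further genes, said so where they appear, were chosen after their values were seen.

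Replicate pairs within a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 71.7, so no library was counted as a duplicate. Islet libraries with the same number deviated together from their group means across genotypes, with correlations of 0.210, 0.362, 0.323 and 0.269 for numbers 3, 4, 7 and 8. Each was over 0.1, so the numbers were treated as pairs, on evidence from the data and not from the labels. The best partner of control library 3 was deleted library 7, and the difference of numbers 4 and 8 from 3 and 7 in both genotypes also raises such correlations, so they do not show that same-numbered libraries share an origin. The model with library number as a block is given where it changes a call.

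The steps were tested on simulated counts drawn from the real means, with 50 genes changed at each of 4 sizes. For Lag3 deletion in islets (15467 genes) edgeR recovered 26%, 70%, 96% and 98% of genes changed by a log2 of 1, 2, 4 and 6. For deletion in the non-draining lymph node (15492 genes) it recovered 6%, 40%, 80% and 96%, and for islets against that node in control mice (15481 genes) 12%, 58%, 90% and 98%. Among unchanged genes edgeR called 6, 5 and 8 in these comparisons, DESeq2 87, 102 and 81, and limma-voom 5, 2 and 8.

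Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter, only the groups compared, the replicate block and each library left out in turn. Added after the data had been seen were a run term, each run alone, the islet contrasts without libraries 4 and 8, DESeq2 with the block, islets alone with the block, the block with an estimated correlation, and a genotype effect averaged over tissues.

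For the T cell receptor table, Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 was used, and figures were drawn with matplotlib 3.10.9. Clonotypes were taken as the table defines them, a clonotype of 2 or more cells was called expanded, and shares have exact binomial 95% intervals for counting error only. No doublet caller was run on this table, and the removal of doublets before deposit is not given in the sources used here. Of 5945 barcodes with a productive beta chain 272 had 2 or more, and the share of expanded cells was also computed over the 3309 barcodes with 1 productive alpha and 1 productive beta chain. The table is 1 mixed sample, so no group comparison was made.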

Results

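Bulk RNA of sorted CD8+ T cells was compared between Lag3-deleted and control NOD mice in islets, pancreatic lymph node and non-draining lymph node, and between tissues within each genotype. The study asks what Lag3 does in the CD8+ T cells of autoimmune diabetes. There were 16 libraries in 6 groups, 4 per genotype from islets and 2 per genotype from each lymph node. Library totals lay between 25972104 and 26054774 reads, and 15691 to 17537 genes were detected per library. Cd8a, the CD8 alpha chain, stood at 2441 ± 847 CPM in control islets and 2671 ± 895 CPM in Lag3-deleted islets (SD, n = 4 each). Across libraries Cd4 was at most 5.46 CPM and Cd3e, a subunit of the CD3 complex, at least 1108 CPM. Low as it was, Cd4 lay apart by genotype, with 0 to 46 reads in the 8 control and 48 to 140 in the 8 deleted libraries, a split noted after its values were seen. It stood at 0.795 ± 0.940 against 3.22 ± 1.60 CPM in control and deleted islets (n = 4 each), 0.0366 ± 0.0518 against 2.07 ± 0.301 CPM in the pancreatic node and 0 against 1.95 ± 0.203 CPM in the non-draining node (n = 2 each). Cd4 is a neighbour of Lag3 (ENSMUSG00000023274; GRCm38 chromosome 6, 124864544 to 124888369), and it passed in none of the 3 tissues (edgeR, adjusted p = 1 in each). Mitochondrially encoded reads made up 3.48% to 4.97%. The first principal component held 29.8% of the variance and the next one 8.41%.

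Lag3, an inhibitory receptor that binds MHC class II (ENSMUSG00000030124; GRCm38 chromosome 6, 124904213 to 124911853), was read in every library first. In control islet libraries 3, 4, 7 and 8 it stood at 3.88, 83.9, 0 and 134 CPM. In Lag3-deleted islet libraries of the same numbers it stood at 0.078, 56.6, 0 and 62.2 CPM. It was 2.84 and 0 CPM in control pancreatic lymph node, 2.01 and 0 CPM in the deleted one, and 0 in all 4 non-draining lymph node libraries. Islet means were 55.4 ± 65.0 CPM in control and 29.7 ± 34.4 CPM in deleted libraries, a log2 fold change of −0.90 (SE 2.14, adjusted p = 1, edgeR). Without control library 8 that value was 0.022. Reads over the whole gene were counted, and the deleted part is not given in the sources used here, so these values do not check the deletion.

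Islet libraries of one group differed widely from each other, and did so by number in both genotypes. Pdcd1, which encodes the inhibitory receptor PD-1, stood at 836 and 821 CPM in control libraries 4 and 8 but at 17.6 and 23.0 CPM in control libraries 3 and 7. In deleted libraries it was 691 and 592 CPM in numbers 4 and 8, and 49.9 and 54.9 CPM in numbers 3 and 7. Ccr7, the lymph node homing receptor of naive T cells, ran the other way, at 182 and 228 CPM in control libraries 4 and 8 and 1415 and 1728 CPM in 3 and 7. Deleted libraries 4 and 8 held 278 and 315 CPM of Ccr7, and deleted libraries 3 and 7 held 1286 and 1545 CPM. Pdcd1 and Ccr7 were picked to show this after their values were seen.

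**Figure D1:**
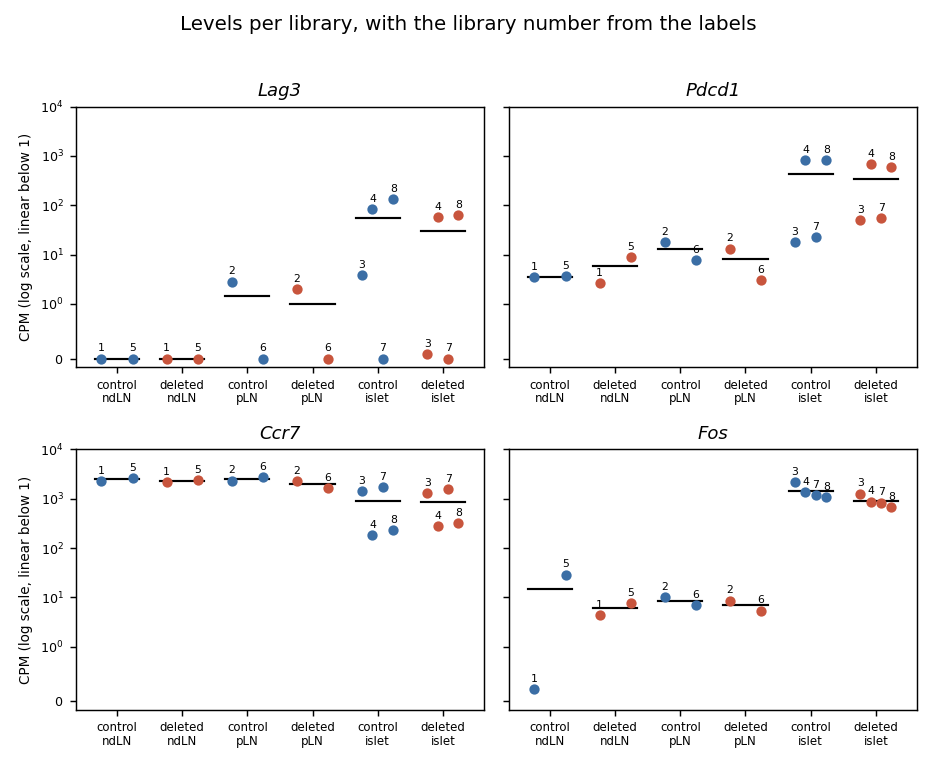
CPM of Lag3, Pdcd1, Ccr7 and Fos in each of the 16 libraries by tissue and genotype, each point marked with its library number. Pdcd1 reached 592 to 836 CPM in islet libraries 4 and 8 and 17.6 to 54.9 CPM in islet libraries 3 and 7, and Fos was at least 682 CPM in all 8 islet libraries against at most 29.0 CPM in lymph nodes.

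In islets, and at the preset correlation only, genes of oxidative phosphorylation passed as slightly higher in Lag3-deleted than in control CD8+ T cells, and genes induced by T cell receptor signalling as lower. Of 42 respiratory chain genes, 40 had positive log2 fold changes, with a median of 0.19 (camera, adjusted p = 5.32e-05, and adjusted p = 0.99 with an estimated correlation). Ndufa6, a complex I subunit, stood at 172 ± 9.84 against 132 ± 28.9 CPM, and Uqcrh, a complex III subunit, at 501 ± 60.7 against 389 ± 87.0 CPM. Of 29 activation genes, 22 had negative values, with a median of −0.40 (camera, adjusted p = 0.0138, and adjusted p = 0.99 with an estimated correlation). Among them Junb, a component of the AP-1 transcription factor, stood at 416 ± 53.4 in deleted and 679.9 ± 74.6 CPM in control islets, and Irf8 at 20.5 ± 7.97 and 45.1 ± 14.7 CPM. No member of either list passed, over all genes or adjusted over the list alone. By camera the respiratory chain list no longer passed without control library 8 (adjusted p = 0.0838). The activation list no longer passed without control library 4 or 8 or deleted library 3 or 7 (adjusted p = 0.106, 0.124, 0.0608 and 0.324). Junb and Dusp1 of this list are among 7 immediate-early and heat-shock genes that were higher in islets than in lymph nodes, a set taken from the calls. Those 7 genes summed to 2855, 2987, 1779 and 1678 CPM in deleted islet libraries 3, 4, 7 and 8 and to 4154, 3681, 2286 and 2702 CPM in the control libraries of the same numbers, lower in the deleted library of all 4 pairs. The mean over the activation list, which shares Junb and Dusp1 with those 7 genes, was lower in all 4 pairs, by −0.45, −0.07, −0.21 and −0.32 log2. Cytokine receptors were lower in all 4 pairs too, and oxidative phosphorylation, ribosomal protein and endocrine lists were higher in all 4. A common direction over the pairs is therefore not particular to activation.

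Genes of T cell exhaustion were split evenly in islets, with 11 of 22 higher and 11 lower in deleted cells, a median of −0.0041, a mean of 0.019 and an adjusted p of 0.968 by camera. Havcr2, which encodes the inhibitory receptor TIM-3, was at 65.5 ± 85.2 in deleted and 28.9 ± 31.0 CPM in control islets (log2 fold change 1.18, SE 1.72). That sign turned to −0.11 without deleted library 4. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was at 119.8 ± 71.5 and 177 ± 157 CPM, with a log2 fold change of −0.56 that became 0.094 without control library 4. Stem-like genes (17 tested, median 0.015, adjusted p = 0.837) and naive and central memory genes (20 tested, median 0.018, adjusted p = 0.968) did not pass by camera. Slamf6, a marker of stem-like cells, stood at 949 ± 385 and 791 ± 206 CPM. Of 24 cytotoxic effector genes 15 were lower, with a median of −0.16 and an adjusted p of 0.287 by camera. Tbx21, the transcription factor T-bet, stood at 52.9 ± 35.1 against 94.7 ± 46.5 CPM, and Cst7, a cathepsin inhibitor, at 445 ± 250.5 against 287 ± 88.7 CPM.

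Proliferation genes gave no direction that held in islets. All 40 had negative values in deleted against control islets, with a median of −0.62, and the list did not pass (camera, adjusted p = 0.105). Without control library 4 the direction turned, with 34 of 40 positive and a median of 0.44 (adjusted p = 0.106). Summed CPM was 982, 4528, 1043 and 2049 in control libraries 3, 4, 7 and 8 and 1740.0, 2294, 844 and 1323 in the deleted ones. The list passed as lower without control library 3 or 7 or deleted library 3 or 4 (adjusted p = 5.36e-05, 8.05e-05, 0.0167 and 0.00164), and as higher without libraries 4 and 8 of both genotypes (adjusted p = 0.00959, 32 of 38 positive). Cdt1, a replication licensing factor, stood at 33.1 ± 15.7 against 70.6 ± 16.7 CPM. Within pairs the mean over this list differed by 3.49, −1.41, −0.50 and −1.50 log2 for numbers 3, 4, 7 and 8. Cytokine receptor genes had 26 of 34 members lower (median −0.09, adjusted p = 0.0838 by camera), among them Il18rap, part of the interleukin-18 receptor, at 39.3 ± 19.0 against 94.0 ± 53.3 CPM. Ribosomal protein genes had 31 of 40 higher (median 0.14, adjusted p = 0.0838), and interferon response genes 27 of 41 (median 0.11, adjusted p = 0.177). By camera the adjusted p was 0.999 for tissue residency, 0.571 for NK receptors, 0.542 for chemokine receptors and 0.961 for glycolysis. For markers of other cells it was 0.287 for CD8 T cells, 0.968 for CD4 T cells, 0.837 for B cells, 0.557 for myeloid cells and 0.837 for MHC class II. It was 0.815 for NK and gamma-delta T cells, 0.542 for endocrine cells, 0.968 for acinar cells, 0.968 for endothelial cells (3 of 12 genes tested), 0.968 for erythroid cells (1 of 8 tested) and 0.837 for mitochondrially encoded genes. Median, mean and test differed in sign for exhaustion, naive and central memory, tissue residency, glycolysis, myeloid, endothelial and erythroid lists.

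No single gene passed for Lag3 deletion in islets (edgeR, 0 higher and 0 lower, 701 at an unadjusted p under 0.05, lowest adjusted p = 0.793). DESeq2 called 3 higher and 8 lower and limma-voom 0. Dld, an enzyme of mitochondrial 2-oxoacid dehydrogenases (ENSMUSG00000020664; chromosome 12, 31331416 to 31351585), had that lowest value, at 117 ± 15.9 in deleted and 228 ± 20.6 CPM in control islets (log2 fold change −0.97, SE 0.16). Groups did not overlap in 282 genes, 1.75% of those tested, against 2.86% by chance. With library number as a block, 0 genes and 5 lists passed. Those lists were oxidative phosphorylation (7.85e-09), ribosomal proteins (6.1e-05), T cell receptor activation (5.11e-03), cytokine receptors (0.0218) and CD8 T cell markers (0.0438), as adjusted p-values by camera. With an estimated correlation beside the block, 0 lists passed. Against 2 lists in the model with all libraries, 4 passed without control library 3, 8 without control 7, 0 without control 8, 7 without deleted 4 and 1 without deleted 7. Within run 11 there was 1 such list and within run 9 there were 4, with 0 genes in each.

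**Figure D2:**
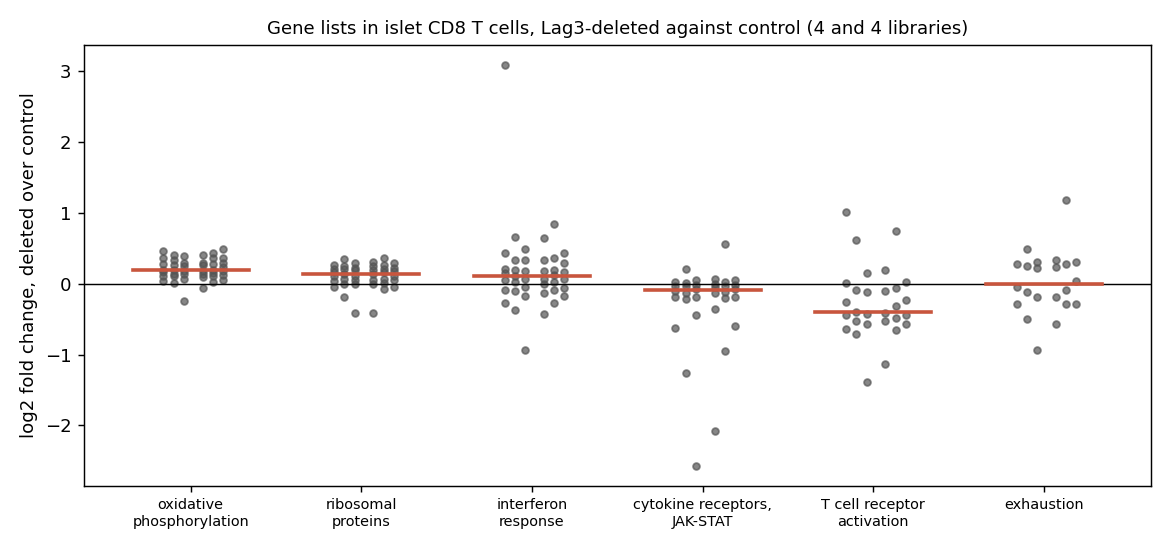
Log2 fold changes of single genes, Lag3-deleted over control in islets, for 6 gene lists, with a red line at each median. Oxidative phosphorylation lies around a median of 0.19, T cell receptor activation around −0.40 and exhaustion around −0.0041. Ribosomal proteins, interferon response and cytokine receptors are also drawn.

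In the pancreatic lymph node, and at the preset correlation only, MHC class II genes and proliferation genes passed as lower and oxidative phosphorylation genes as higher in Lag3-deleted than in control libraries. With an estimated correlation their adjusted p was 0.23, 0.985 and 0.985. Of 7 MHC class II genes 5 had negative values, with a median of −0.58 (camera, adjusted p = 0.0037). H2-Aa, an MHC class II alpha chain, was at 0 in both deleted libraries and at 0.53 and 10.98 CPM, or 14 and 300 reads, in control libraries 2 and 6. H2-Ab1 was at 0 against 0.341 and 2.09 CPM, or 9 and 57 reads, so that control library 6 stood apart for both. These 2 genes passed adjusted over the list alone, 0 did so without control library 6, and neither passed over all genes. The mean log2 CPM of the list was 1.26 and 2.89 in control libraries 2 and 6 and 1.02 and 0.58 in deleted ones, and the list did not pass without control library 6 or deleted library 2 or 6 (adjusted p = 0.281, 0.198 and 0.286). Oxidative phosphorylation had 37 of 42 genes higher, with a median of 0.24 (adjusted p = 0.0037), which turned to −0.05 without control library 6 (adjusted p = 0.561) and was 0.08 without deleted library 2 (adjusted p = 0.821). Atp5j, a subunit of ATP synthase, stood at 288 ± 22.6 against 187 ± 42.9 CPM. Proliferation had 26 of 40 lower, with a median of −0.28 (adjusted p = 0.0142), and did not pass without control library 2 or deleted library 2 (adjusted p = 0.887 and 0.405). Ccnb1, a mitotic cyclin, stood at 0.019 ± 0.0268 against 1.88 ± 1.53 CPM. In the deleted islets, MHC class II genes had 6 of 7 positive values.

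No single gene passed in the pancreatic lymph node (edgeR, 0 called, 414 at an unadjusted p under 0.05), where DESeq2 called 12 higher and 10 lower and limma-voom 0. Ttll1, a tubulin glutamylase subunit (ENSMUSG00000022442; chromosome 15, 83483624 to 83511041), had the lowest adjusted p, 0.559, at 27.6 ± 2.66 in deleted and 5.95 ± 1.62 CPM in control libraries. Groups did not overlap in 26.8% of genes, against 33.3% by chance. Without control library 6, or without deleted library 2, 1 list passed in place of 3.

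In the non-draining lymph node, no gene and no list passed (edgeR, 0 called, 349 at an unadjusted p under 0.05). DESeq2 called 12 higher and 5 lower there, and limma-voom 1 higher. Irak2, a kinase of interleukin-1 and toll-like receptor signalling, had the lowest adjusted p, 0.318, at 19.9 ± 8.91 in deleted and 2.23 ± 1.02 CPM in control libraries (n = 2 each). Dld stood at 119 ± 11.5 against 218 ± 1.71 CPM (log2 fold change −0.87, SE 0.23, adjusted p = 1). The list with the lowest value was proliferation (camera, adjusted p = 0.272), and oxidative phosphorylation, with 32 of 42 genes lower, had an adjusted p of 0.458. Groups did not overlap in 28.2% of genes, against 33.3% by chance. Without control library 5, 1 gene and 2 lists passed. Without control library 1, 1 list passed, and without deleted library 1, 2 did.

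Differences between tissues in the effect of the deletion were tested directly. Oxidative phosphorylation genes were shifted up by the deletion in islets relative to the non-draining lymph node, in 39 of 42 genes, with a median difference of 0.27 (camera, adjusted p = 1.04e-04, and adjusted p = 0.994 with an estimated correlation). Relative to the pancreatic lymph node, MHC class II genes were shifted up in 5 of 7 genes, with a median of 0.54 (adjusted p = 0.00515, and adjusted p = 0.218 with an estimated correlation). H2-Eb1, an MHC class II beta chain, had a difference of 2.85 log2 (SE 1.28). No single gene passed either test (edgeR, 0 called, 466 and 445 at an unadjusted p under 0.05, lowest adjusted p = 1). DESeq2 called 0 against the non-draining node and 2 higher and 6 lower against the pancreatic node. With the block, 3 and 2 lists passed in place of 1 each, with ribosomal proteins added in both (camera, adjusted p = 0.0349 and 0.0377) and CD8 T cell markers against the non-draining node (adjusted p = 0.0134). With an estimated correlation beside the block, 0 lists passed in either interaction. Against the non-draining node the list count was 0 without its control library 1 or its deleted library 5, 4 without its deleted library 1, and 2 without its control library 5. It was also 2 without control islet library 3, 4 or 8, or deleted islet library 7 or 8. Against the pancreatic node it was 3 without its control library 2 or deleted library 2 and 5 without its control library 6. It was 2 without control islet library 4, 3 without control islet library 7 and 2 without deleted islet library 7.

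In control mice 9 genes were called higher in islet CD8+ T cells than in those of the non-draining lymph node. Among them were immediate-early genes and the heat-shock genes Hspa1a and Hspa1b, classes for which no list was fixed. Junb rose 9.90-fold, from 68.7 ± 8.89 (n = 2) to 679.9 ± 74.6 CPM (n = 4), a log2 fold change of 3.31 (SE 0.29, adjusted p = 0.000856, edgeR; ENSMUSG00000052837, chromosome 8, 84976761 to 84978896). Dusp1, a phosphatase that inactivates MAP kinases (ENSMUSG00000024190; chromosome 17, 26505442 to 26508667), rose 43.4-fold to 733 ± 244 CPM (adjusted p = 0.0116). Hspa1a, an inducible HSP70 chaperone (ENSMUSG00000091971; chromosome 17, 34969042 to 34972304), was at 0 in both lymph node libraries and 305 ± 222 CPM in islets, at least 2717-fold higher (adjusted p = 0.0293). Its near-identical neighbour Hspa1b stood at 162 ± 100.1 against 0.0567 ± 0.0801 CPM (adjusted p = 0.0122), and the split of reads between the pair is uncertain. Klf6, a zinc finger transcription factor, rose 4.17-fold, and Ppp1r15a, which directs dephosphorylation of eIF2 alpha, rose 12.1-fold (adjusted p = 0.0297 and 0.0327). Rgs2, a regulator of G protein signalling, rose 10.4-fold, Sik1, a salt-inducible kinase, 7.74-fold, and Tagap 4.26-fold (adjusted p = 0.0451, 0.0451 and 0.036). These 9 genes were higher in all 4 islet libraries than in both lymph node libraries, and 0 genes fell by edgeR at this threshold. At an unadjusted p under 0.05 there were 1509 genes, and DESeq2 called 432 higher and 83 lower. DESeq2 kept all 9 calls, while limma-voom kept Dusp1, Junb, Klf6 and Ppp1r15a alone. Neither Hspa1a nor Hspa1b was called by limma-voom in any comparison of islets with a node.

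Gene lists of T cell programs also differed between these tissues at the preset correlation, several of them mainly through islet libraries 4 and 8. All 22 exhaustion genes had positive values against the non-draining lymph node, with a median log2 fold change of 3.51, although 0 passed singly and 7 did adjusted over the list alone. Summed exhaustion genes were 8393 and 9308 CPM in control islet libraries 4 and 8 but 1857 and 1655 CPM in 3 and 7, against 1718 and 1842 CPM in the node. Their mean log2 CPM was 7.69 and 7.74 in 4 and 8, 4.43 and 4.23 in 3 and 7, and 2.28 and 2.39 in the node. Lgals3, a galectin, was at 0 in the lymph node and 229 ± 214 CPM in islets (at least 2044-fold), and Entpd1, the ectonucleotidase CD39, was at least 761-fold higher (adjusted p = 0.193 and 0.217, not passing). In the control pancreatic node Lgals3 stood at 0.604 ± 0.854 CPM. Of 24 cytotoxic genes 23 had positive values, with a median of 4.92, or 3.94 with genes at 0 set to their bound, and 16 passed adjusted over the list alone. Ccl5, a chemokine of effector T cells, stood at 4031 ± 3521 against 61.4 ± 12.8 CPM, and Ifng, the cytokine interferon gamma, at 317 ± 259.9 CPM against 0 (adjusted p = 0.19 and 0.134). Activation genes were higher in 26 of 29 (median 1.89), of which 2 passed over all genes and 12 adjusted over the list alone. Fos stood at 1435 ± 487 against 14.6 ± 20.4 CPM and Cd69, an early activation and retention marker, at 696 ± 183 against 272 ± 60.4 CPM (adjusted p = 0.113 and 0.104). All 20 naive and central memory genes were lower, with a median of −0.71, and 0 passed in either count. Their mean log2 CPM was 5.37 and 5.56 in libraries 4 and 8, while 8.03 and 8.24 in libraries 3 and 7 stood close to 8.16 and 8.24 in the node. Ccr7 stood at 888 ± 799 against 2458 ± 246 CPM.

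By camera, adjusted p-values in this comparison were 2.58e-23 for activation, 6.86e-17 for cytotoxicity, 4.88e-11 for exhaustion, 6.4e-11 for tissue residency and 4.28e-06 for naive genes. With an estimated correlation the adjusted p was 0.0125, 0.0557, 0.203, 0.0532 and 0.33 for the same lists, so that of these only activation held. The activation list includes immediate-early genes such as Fos, Junb and Dusp1, which digestion of islets at 37 °C may raise. In no comparison of islets with a node can activation and digestion be told apart. Proliferation (39 of 40 genes higher, median 3.49), NK receptors (17 of 19, median 4.04, or 3.54 at the bound) and interferon response (35 of 41, median 0.61) had adjusted p = 7.83e-07, 1.64e-06 and 3.36e-05. With an estimated correlation their adjusted p was 0.372, 0.148 and 0.139, and 0, 1 and 2 members passed adjusted over the list alone. Mean log2 CPM of proliferation genes was 6.30 and 4.73 in islet libraries 4 and 8 but 1.13 and 1.23 in 3 and 7, against 1.30 and 1.27 in the node. For NK receptors it was 2.86 and 3.95 in 4 and 8, 1.25 and 0.78 in 3 and 7, and −0.44 and −0.57 in the node. Interferon response genes ran otherwise, summing to 3782 and 3906 CPM in libraries 4 and 8 and 6876 and 6756 CPM in 3 and 7, against 4283 and 3845 CPM in the node. Their mean log2 CPM was 4.98 and 5.04 in 4 and 8, 5.17 and 5.73 in 3 and 7, and 4.78 and 4.29 in the node. Without libraries 4 and 8, the adjusted p by camera was 0.826 for proliferation and 0.34 for naive genes, which no longer passed, and 5.25e-05 for exhaustion. Chemokine receptors (median 1.08, adjusted p = 0.00746) and cytokine receptors (median 0.27, adjusted p = 0.027) each had an adjusted p = 0.0791 with an estimated correlation. Of the 14 lists that passed, 2 held with an estimated correlation. Mx1, an interferon-induced GTPase, stood at 31.2 ± 12.9 against 3.37 ± 0.633 CPM, and Ccna2, a cyclin of S and G2 phase, at 64.4 ± 91.8 against 0.891 ± 0.779 CPM.

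Markers of other pancreatic and immune cells were higher in the same islet libraries. All 17 acinar genes had positive values in control islets against the non-draining lymph node, with a median of 9.33, or 5.36 at the bound (camera, adjusted p = 1.12e-19, and adjusted p = 0.0125 with an estimated correlation). Their summed level was 1.12 to 13.7 CPM in lymph node libraries and 58.4 to 322 CPM in islet libraries, and 10 passed adjusted over the list alone. Ctrb1, a chymotrypsinogen, stood at 15.2 ± 11.1 CPM against 0. Myeloid markers summed to 4.17 to 12.3 CPM in lymph nodes and 23.3 to 294 CPM in islets (adjusted p = 0.000722, and adjusted p = 0.0758 with an estimated correlation). Endocrine markers summed to 0 in lymph nodes and 0.0384 to 30.4 CPM in islets (adjusted p = 0.00746, and adjusted p = 0.227 with an estimated correlation). MHC class II genes, which include Cd74 at 58.7 ± 35.5 against 8.53 ± 8.00 CPM, had an adjusted p = 0.00208, and adjusted p = 0.064 with an estimated correlation.

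Junb and Dusp1 kept their calls in control islets against the non-draining lymph node whichever single library was left out. With only the 2 groups compared in the fit, Junb alone passed of the 9 genes (adjusted p = 0.0185, edgeR), and Dusp1 did not (adjusted p = 0.254). Without lymph node library 1 or 5, which leaves a lone node library, most of the 9 genes lost their calls. Of the 9, 4 stayed called without islet library 3, 3 without 4, 9 without 7 and 5 without 8. With new genes counted, 5, 6, 14 and 5 passed in these fits. Within run 11 and within run 9 alone, with 1 lymph node library each, 0 genes passed.

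In Lag3-deleted mice, 7 genes were called higher in islets than in the non-draining lymph node and 5 lower. The 7 are heat-shock and immediate-early genes that were also called in control mice. Junb rose 5.41-fold to 416 ± 53.4 CPM (adjusted p = 0.0149, edgeR), Dusp1 30.6-fold to 525 ± 199 CPM (adjusted p = 0.0191) and Ppp1r15a 10.9-fold, Rgs2 11.4-fold and Klf6 3.74-fold (adjusted p = 0.0337 each). Hspa1a was at 0 in the lymph node and 214 ± 128 CPM in islets, at least 1922-fold higher (adjusted p = 0.0299), and Hspa1b reached 111 ± 64.8 CPM (adjusted p = 0.0191). Tubb4b, a beta tubulin, fell from 321 ± 27.9 to 111 ± 13.5 CPM (adjusted p = 0.0337), Il16, a CD4-binding cytokine, from 473 ± 72.6 to 248 ± 29.8 CPM (adjusted p = 0.0381) and Cdc42se1 from 565 ± 61.9 to 291 ± 23.3 CPM (adjusted p = 0.0299). Tmem19 and Tnfaip8l2 also fell, to 23.3 ± 4.39 and 134 ± 15.1 CPM (adjusted p = 0.0381 and 0.0493). DESeq2 kept all 12 calls, while limma-voom kept 8 and dropped Hspa1a, Hspa1b, Rgs2 and Tmem19. All 7 genes that rose were among the 9 of control mice, where 0.00392 shared genes would be due by chance if the calls were independent. The genotypes share no library, but both contrasts come from 1 fit with a common spread per gene. Islets of both genotypes were also digested, so the overlap is no independent support. The test of a difference between genotypes called 0 genes by edgeR, with 466 at an unadjusted p under 0.05, and 0 by DESeq2.

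By list, exhaustion genes were also higher in deleted islets, 22 of 22, with a median of 3.46 (camera, adjusted p = 1.81e-13, and adjusted p = 0.159 with an estimated correlation) and 11 passing adjusted over the list alone. Summed exhaustion genes were 10150.2 and 7226 CPM in deleted islet libraries 4 and 8 but 1949.5 and 1621 CPM in 3 and 7, against 1733 and 1450.5 CPM in the node. Without libraries 4 and 8 the exhaustion list had an adjusted p of 4.49e-09 by camera. Nr4a2, a nuclear receptor induced by T cell receptor signalling, stood at 94.9 ± 89.9 against 0.0184 ± 0.026 CPM. Activation had 28 of 29 higher (median 1.63, or 1.60 at the bound, adjusted p = 1.69e-17, and adjusted p = 0.0352 with an estimated correlation). Acinar, tissue residency, myeloid and MHC class II lists also held with an estimated correlation, at adjusted p = 0.0127, 0.0362, 0.0352 and 0.0432, so that 5 of 14 lists held. Cytotoxic genes had 22 of 24 higher (median 3.99, or 2.53 at the bound, adjusted p = 1.48e-14, and adjusted p = 0.0575 with an estimated correlation). Oxidative phosphorylation had 39 of 42 higher (median 0.37, adjusted p = 2.04e-05, and adjusted p = 0.563 with an estimated correlation). Naive and central memory genes were lower in 19 of 20 (median −0.81, adjusted p = 3.75e-06, and adjusted p = 0.346 with an estimated correlation). Their mean log2 CPM was 5.39 and 5.88 in libraries 4 and 8 but 7.91 and 8.13 in 3 and 7, against 8.20 and 8.27 in the node. In place of 12 genes, 1 passed with only the groups compared in the fit, which was Fos and none of the 12, and 0 passed without lymph node library 1 or 5, 4 without islet library 3 or 4 and 5 without islet library 8. Without islet libraries 4 and 8 together 2 passed, which were Tubb4b and Gbp2, the latter not among the 12. No immediate-early or heat-shock gene stayed called in that fit.

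Against the pancreatic lymph node, which drains the pancreas, 9 genes were called higher in control islets and 2 lower. Those higher include immediate-early, heat-shock and stress-response genes, classes for which no list was fixed. Junb rose 7.70-fold from 88.3 ± 28.7 CPM (adjusted p = 0.00252, edgeR), Dusp1 58.0-fold from 12.6 ± 2.36 CPM (adjusted p = 0.00668), Rgs2 14.3-fold, Ppp1r15a 11.5-fold and Klf6 4.53-fold (adjusted p = 0.0238, 0.0284 and 0.0224). Hspa1a and Hspa1b were at 0 in the node, at least 2728-fold and 1447-fold higher in islets (adjusted p = 0.0234 and 0.00822). Gadd45b, a stress-induced gene, rose 15.7-fold to 169.6 ± 77.5 CPM, and Atf4, a transcription factor of the integrated stress response, 2.42-fold to 420.5 ± 52.4 CPM (adjusted p = 0.0395 each). Mir142hg, host gene of the microRNA miR-142, fell from 26.9 ± 13.2 to 3.24 ± 0.962 CPM (adjusted p = 0.0408) and AI467606 from 656 ± 23.7 to 233 ± 65.5 CPM (adjusted p = 0.0284). DESeq2 kept all 11 calls, while limma-voom kept 6 and dropped Hspa1a, Hspa1b, Gadd45b, Rgs2 and Mir142hg. Without islet libraries 4 and 8, only Dusp1, Hspa1b and Junb of the 11 stayed called. Gzmk, a granzyme, was at 0 in the node and 491 ± 393 CPM in islets, at least 4394-fold (adjusted p = 0.194, not passing). In the control non-draining node Gzmk stood at 5.14 ± 7.26 CPM, so the bound holds for the pancreatic node libraries only.

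Exhaustion genes in control islets were higher than in the pancreatic lymph node in 22 of 22 (median 3.64, camera, adjusted p = 5.59e-11, and adjusted p = 0.254 with an estimated correlation), cytotoxic genes in 22 of 24 (median 5.84, or 5.15 at the bound, adjusted p = 6.52e-17, and adjusted p = 0.0555 with an estimated correlation). Summed exhaustion genes were 8393 and 9308 CPM in islet libraries 4 and 8 but 1857 and 1655 CPM in 3 and 7, against 1673 and 1508 CPM in the pancreatic node. Only activation (28 of 29 higher, median 1.73, or 1.54 at the bound) and acinar markers held with an estimated correlation, both at adjusted p = 0.0129. Stem-like genes passed at the preset correlation (11 of 17 higher, median 0.35, adjusted p = 0.00865, and adjusted p = 0.127 with an estimated correlation). Cxcr3, a chemokine receptor of effector and memory T cells, stood at 511 ± 351 against 112 ± 24.3 CPM. In place of 11 genes, 1 passed with only the groups compared in the fit, which was Fos and none of the 11. Of the 11 genes called, 0 stayed called without node library 2, 1 (Junb) without node library 6 and 5 (Junb, Dusp1, Klf6, Hspa1a and Hspa1b) without islet library 8, and 0 within each run alone.

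Lag3-deleted islets had 9 genes higher and 3 lower than the pancreatic lymph node. Junb rose 6.53-fold, Dusp1 35.2-fold, Rgs2 15.2-fold, Gadd45b 20.7-fold, Ppp1r15a 9.55-fold and Klf6 4.95-fold (edgeR, adjusted p = 0.00555, 0.0133, 0.02, 0.0206, 0.0359 and 0.0133). Hspa1a and Hspa1b rose from 0.019 ± 0.0268 CPM each, which is 1 read, to 214 ± 128 and 111 ± 64.8 CPM (adjusted p = 0.0206 and 0.0133). Gsdmd, the pore-forming protein of pyroptosis, rose 2.27-fold to 107 ± 9.28 CPM (adjusted p = 0.0206). Tmem19, Mir142hg and Tubb4b fell to 23.3 ± 4.39, 4.26 ± 1.99 and 111 ± 13.5 CPM, from 70.5 ± 8.64, 38.8 ± 6.85 and 298 ± 8.95 CPM (adjusted p = 0.0133, 0.0299 and 0.0359). Of the genes that rose, 8 were shared with the 9 of control mice, and of those that fell, Mir142hg was shared. By chance 0.00504 of those that rose would be shared if the calls were independent, which the common fit does not ensure. DESeq2 kept all 12 calls, while limma-voom kept 8 and dropped Gadd45b, Hspa1a, Hspa1b and Rgs2.

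In this comparison of deleted islets with the pancreatic lymph node, 8 of 15 lists held with an estimated correlation, among them activation (adjusted p = 0.0267), cytotoxicity (0.0446), tissue residency (0.0446), acinar (0.0113) and myeloid markers (0.0267). Cytotoxic genes summed to 32271 and 20314 CPM in islet libraries 4 and 8, 7844 and 5387 CPM in 3 and 7, and 4057 and 3601 CPM in the node. For tissue residency the sums were 8479 and 5977 CPM, 2682 and 2402 CPM, and 1659 and 1675 CPM. Stem-like genes were higher in 13 of 17 (median 0.93, camera, adjusted p = 0.000881, and adjusted p = 0.0478 with an estimated correlation), with Slamf6 at 949 ± 385 against 468 ± 28.4 CPM. Exhaustion genes, 22 of 22 higher with a median of 2.96, passed at an adjusted p of 7.06e-12, and adjusted p = 0.178 with an estimated correlation. Their summed level was 10150.2 and 7226 CPM in libraries 4 and 8 but 1949.5 and 1621 CPM in 3 and 7, against 1619 and 1569.95 CPM in the node. In place of 12 genes, 1 passed with only the groups compared in the fit, which was Fos and none of the 12. Without node library 2 or 6, which leaves a lone node library, most of the 12 lost their calls. Within each run alone, and without islet libraries 4 and 8, 0 passed.

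**Figure D3:**
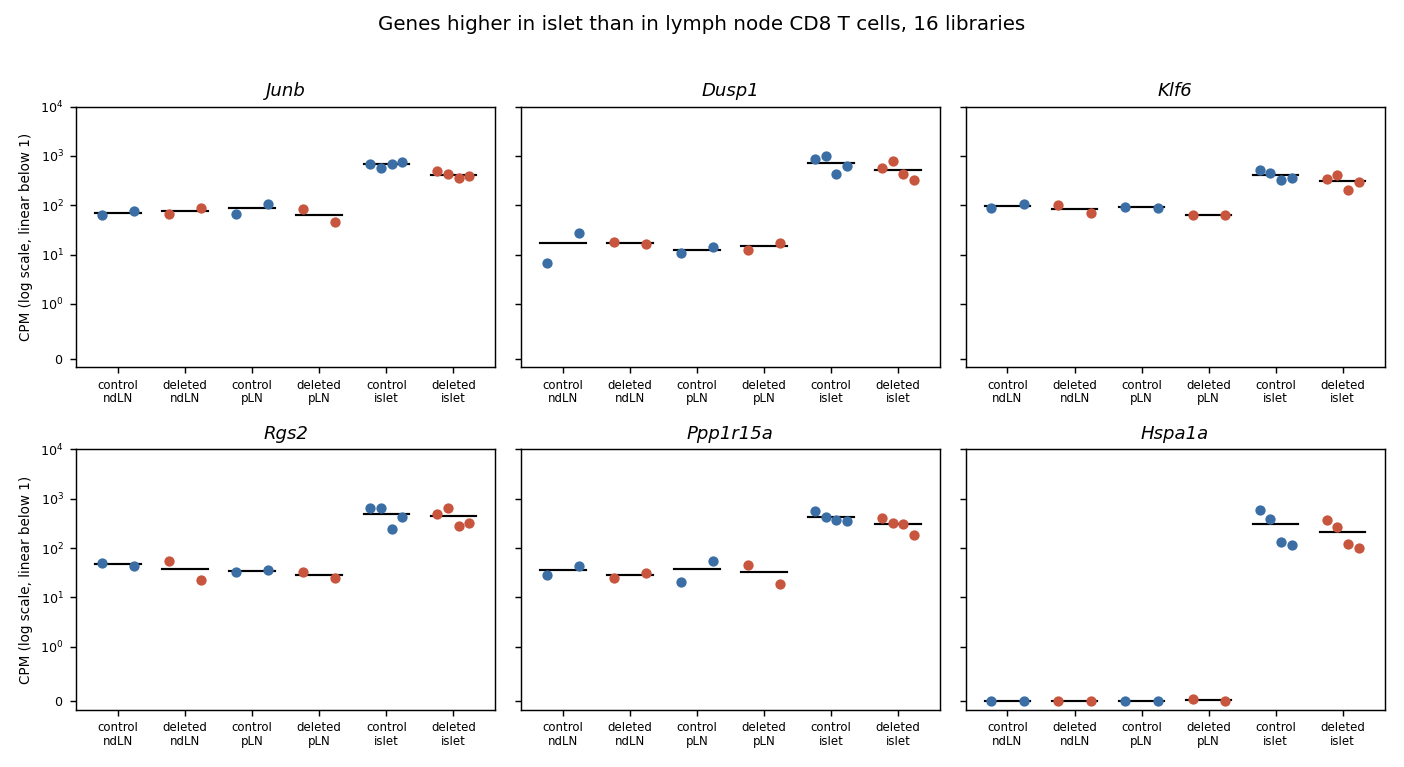
CPM of Junb, Dusp1, Klf6, Rgs2, Ppp1r15a and Hspa1a per library, on an axis that is logarithmic above 1 and linear below it, with control in blue, Lag3-deleted in red and lines at group means. Junb means were 679.9 and 416 CPM in control and deleted islets against 63.7 to 88.3 CPM in the lymph node groups.

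No single gene passed between the pancreatic and non-draining lymph nodes. In control mice 0 genes passed (edgeR, 384 at an unadjusted p under 0.05, DESeq2 19 higher and 11 lower, limma-voom 0), and in deleted mice 0 passed (369 at an unadjusted p under 0.05, DESeq2 7 higher and 11 lower, limma-voom 2 lower). In control mice interferon response genes (29 of 41 higher, median 0.28) and MHC class II genes (6 of 7 higher, median 0.49) were higher in the pancreatic node, and oxidative phosphorylation genes lower (40 of 42, median −0.15). Each had an adjusted p of 0.0228 by camera, and adjusted p = 0.993, 0.578 and 0.993 with an estimated correlation. Isg15, an interferon-induced ubiquitin-like protein, stood at 17.8 ± 1.08 against 7.92 ± 2.90 CPM, and Irf7, a transcription factor of the interferon response, at 123 ± 3.08 against 93.2 ± 16.2 CPM. Mx1 ran the other way, at 0.902 ± 0.847 against 3.37 ± 0.633 CPM. In deleted mice no list passed, with oxidative phosphorylation lowest at an adjusted p of 0.236, and Art2b, an ADP-ribosyltransferase, stood at 106 ± 17.0 against 32.0 ± 3.45 CPM. Without pancreatic node library 6, 1 list passed in control mice in place of 3. In deleted mice 2 lists passed without non-draining library 1, 2 without pancreatic library 2 and 1 without pancreatic library 6.

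The T cell receptor table held 23834 contigs of 7828 cell barcodes, of which 6959 carried a clonotype. It mixes cells of both genotypes and of islets and lymph nodes, so values describe the mixture. There were 5534 clonotypes, and 345 of 2 or more cells held 1770 cells, 25.4% of those with a clonotype (24.4% to 26.5%). The largest clonotype had 67 cells, 0.963% (0.747% to 1.22%). Among 4807 cells with a productive alpha chain, TRAV16N was used by 16.7% (15.6% to 17.7%) and TRAJ42 by 7.84% (7.10% to 8.64%). Among 5945 cells with a productive beta chain, TRBV16 was used by 12.7%, TRBV13-3 by 12.0%, TRBV3 by 11.1% and TRBJ2-7 by 25.1% (24.0% to 26.2%). The alpha chain found in most cells, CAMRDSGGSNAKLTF with TRAV16N and TRAJ42, occurred in 105 cells, and the beta chain found in most cells, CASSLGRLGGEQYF with TRBV3 and TRBJ2-7, in 100.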

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

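Gaps between libraries and tests of a difference between tissues were set before the data were examined, while the classes of receptor contigs were listed after the table had been read. Of 334 sets of 4 islet libraries tested for a library far from the other 3, 13 passed Dixon's 95% critical value, and chance alone gives about 5% of sets.

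Among control islet libraries, Ctbs was 11.3 CPM in number 8 against 17.3 to 18.2 CPM in the others. Gcg, the glucagon gene, was 27.6 CPM in number 8 against 0.0384 to 2.78 CPM. In number 7, Irf7 was 131 CPM against 117 to 119 CPM, and Lyz2, a lysozyme of myeloid cells, was 239.5 CPM against 0.0392 to 10.5 CPM. In number 3, Mx1 was 11.8 CPM against 37.3 to 38.0 CPM and Trim30a was 239 CPM against 199 to 201 CPM. Rrm1, a subunit of ribonucleotide reductase, was 162 CPM in number 4 against 71.9 to 87.0 CPM. The mean log2 CPM of erythroid genes, 1 gene tested, was −0.40 in number 4 against −3.70, and that of myeloid genes was −1.04 in number 3 against 1.17 to 1.36.

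Among Lag3-deleted islet libraries, S1pr5 was 0.416 CPM in number 4 against 0 to 0.0392 CPM, and Tagap was 216 CPM in number 3 against 171 to 178 CPM. The mean log2 CPM of interferon response genes was 6.03 in number 7 against 5.17 to 5.31. The 10 most abundant genes took 9.62% of reads in number 8 against 10.2% in the others.

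The effect of the deletion differed between islets and the non-draining lymph node for oxidative phosphorylation (camera, adjusted p = 0.000104), and between islets and the pancreatic lymph node for MHC class II (adjusted p = 0.00515). Neither held with an estimated correlation, at an adjusted p of 0.994 and 0.218.

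In the T cell receptor table, 6395 of 23834 contigs joined segments of more than 1 chain. They lay in 6072 barcodes, 77.6% of all, and 4593 of them were of 1 kind, which was never productive and had a median of 3 unique molecular identifiers. Immunoglobulin contigs numbered 100 heavy, 47 kappa and 13 lambda. Gamma and delta receptor contigs numbered 19 and 15. These classes lie outside the chains compared in the report, and with no control sample no value separates them from background.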

How the results depend on the processing

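Run terms, single runs, leaving out islet libraries 4 and 8, DESeq2 with a block, islets alone with a block and the block with an estimated correlation were chosen after seeing the data. Of 252 gene and contrast pairs named, 44 were called and 0 of these turned sign, while 3 not called did. Among their values under other settings 3310 kept their side of the threshold, 348 lost a call, 182 gained one and 6 turned sign. All 348 losses fall on the 44 called pairs, since only those could lose a call. The 3310 include pairs that were not called in the main model and stayed so. Counts of genes stayed within 1.5 times in 117 settings and moved further in 49, and counts of lists did so in 116 and 61. Counts of 0 that stayed at 0 are among those that stayed. The main model called genes only in the contrasts of islets with a node, so the 117 say little about how stable a call is. Where a count moved, the cause was not tested. Each lymph node group has 2 libraries, so leaving out 1 leaves a lone sample assumed to vary like the others, and the equalised totals hide the depth that limits genes at low counts.

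DESeq2 called 11 genes for deletion in islets, 22 in the pancreatic and 17 in the non-draining lymph node, where edgeR called 0. It called 515 and 507 for islets against the non-draining node in control and deleted mice, 456 and 459 against the pancreatic node, and 30 and 18 between the nodes. It called 8 for the interaction with the pancreatic node. On simulated data, which lacked the split of islet libraries by number, DESeq2 also called more unchanged genes than edgeR, 87 against 6 for deletion in islets. Limma-voom called 1 gene for deletion in the non-draining node, 22 for deleted islets against that node and 2 between the nodes in deleted mice. For the interaction with the pancreatic node it called 0 lists.

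With the replicate block on library number, lists for deletion in islets numbered 5, and 3 and 2 for the interactions with the non-draining and pancreatic nodes. Islets alone with the block gave 8 lists. DESeq2 with the block called 64, 33 and 43 genes for deletion in islets, pancreatic and non-draining node, and 27 and 15 for the interactions. The block with an estimated correlation left 0 lists for deletion in islets and in the pancreatic node and 0 for both interactions. Same-numbered libraries correlated by 0.0485 in the non-draining and 0.0240 in the pancreatic node. There they also share a run. With 2 libraries per group, these low values do not settle whether the numbers mark pairs. In the pancreatic node the block added mitochondrially encoded genes to the 3 lists for deletion (camera, adjusted p = 0.0322). The block changed no other call by edgeR or camera. Pairing by library number was not possible for the contrasts between tissues, because islets and lymph nodes share no numbers. With a run term, islets against the non-draining node kept 6 of 9 called genes in control and 9 of 12 in deleted mice. Against the pancreatic node 11 of 11 and 10 of 12 were kept. In the same order 2, 1, 3 and 1 genes were new.

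With an estimated correlation, and with fry, 0 lists passed for deletion in islets, deletion in the pancreatic node, the nodes in control mice and both interactions. For islets against the non-draining node 2 and 5 lists passed with the estimated correlation in control and deleted mice, and 8 and 8 with fry. Against the pancreatic node 2 and 8 passed with the estimated correlation, and 6 and 9 with fry.

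With only the groups compared, 1 gene passed in each of the 4 contrasts of islets with a node. Within run 11 and within run 9, 0 genes passed in each of these. A run term gave 4 lists for deletion in islets and 1 between the nodes in deleted mice, and single runs gave 1 list in run 11 and 4 in run 9 for deletion in islets. Without islet libraries 4 and 8, deletion in islets gave 1 gene, deleted islets gave 2 genes against the non-draining and 0 against the pancreatic node, and the interaction with the non-draining node gave 2 lists. Control islets then gave 11 genes against each node. Of the genes called with all libraries only Dusp1, Hspa1b and Junb were kept there, and 8 genes were new in each.

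Leaving out each library in turn, lists for deletion ranged from 0 to 8 in islets, 1 to 3 in the pancreatic and 0 to 2 in the non-draining node, where genes ranged from 0 to 1. Genes for islets against the non-draining node ranged from 4 to 14 in control and 0 to 8 in deleted mice, and against the pancreatic node from 0 to 15 and 0 to 11. Lists between the nodes ranged from 1 to 4 in control and 0 to 2 in deleted mice. Interaction lists ranged from 0 to 4 for the non-draining and 1 to 5 for the pancreatic node.

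For deletion in islets, Havcr2 turned from 1.18 to −0.68 by limma-voom and −0.97 without libraries 4 and 8, and ranged from −0.11 to 1.99 with single libraries left out. Tnfrsf9 became 0.24 without libraries 4 and 8 and ranged from −0.90 to 0.094, and Lag3 ranged from −1.55 to 0.022. The share of expanded T cell receptor cells, 25.4%, became 30.2% by beta chain sequence, 30.0% with paired chains, 29.7% with 1 alpha and 1 beta chain, and 16.7% with 5 or more cells.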

Other observations

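All tests of the islet library pattern, of the stress genes and of a chromosomal segment, the count of genes over other splits of the islet libraries, the count of genes in every tissue over splits that part the islet pairs, and the averaged effect were chosen after the result was seen, and the counts of lists over other islet splits and of genes in every tissue over all splits were chosen before.

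The alpha chain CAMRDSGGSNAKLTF was carried by 105 cells through 4 nucleotide sequences. Among 80 of these cells with 1 alpha and 1 beta chain it was joined to 19 distinct beta chains, the commonest in 16 cells. Each of the other 9 alpha chains found in most cells had 1 nucleotide sequence and 1 to 4 partners, among 4 to 68 cells with 1 alpha and 1 beta chain. The beta chain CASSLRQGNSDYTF, in 92 cells, had 8 partners, and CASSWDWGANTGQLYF, in 86 cells, had 1. No antigen was assigned to any of these chains.

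Islet libraries numbered 4 and 8 lay apart from those numbered 3 and 7 in both genotypes. Run alone is argued against as the cause by the layout, since numbers 3 and 4 are of run 11 and numbers 7 and 8 of run 9. Run means differed by 0.118 of the smaller range within a run on the first principal component. With the pattern already seen, that value follows from the layout and adds no support. Dilution of numbers 4 and 8 by other cells is argued against, since CD8 T cell markers summed to at least 19080 CPM there and at most 17022 CPM in numbers 3 and 7, and dilution of 3 and 7 is argued against as the whole cause, since exhaustion genes differed by at least 3.71 times between the nearest libraries and CD8 T cell markers by at most 1.54 times. A mix-up of numbers 3 and 7 with lymph node libraries is argued against, since acinar markers summed to at least 75.6 CPM in those libraries and at most 13.7 CPM in lymph nodes. A smaller share of other cells in 3 and 7, or a difference in sorted subset that the labels do not name, may remain and was not tested.

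In all 3 tissues, 12 genes had genotypes that did not overlap in one direction, 7 higher and 5 lower in deleted mice. Of 1260 splits within tissue 305 gave as many (median 8, highest other 169, in a split that does not part all islet pairs), and of the 288 that part all 4 islet pairs 21 did (median 6, highest other 22), so chance is not excluded for the count. Picked after their values were seen, 1810053B23Rik and Gm5678, both on chromosome 16, had 0 to 1 and 32 to 77 counts in 8 control and 22 to 451 and 0 to 3 in 8 deleted libraries, Cd4 and Irak2 on chromosome 6 had 0 to 46 and 40 to 219 against 48 to 140 and 275 to 714, and Dld on chromosome 12 had 4183 to 6383 against 2377 to 3816. A segment linked to the deletion that holds all 12 is argued against, since 10 lay on other chromosomes than Lag3. Cd4 was the 1 of them among 43 tested genes within 1 Mb of Lag3 (p = 0.0316, one-sided Fisher's exact test, run with its place known). Control mice are floxed too, so a segment carried with the floxed allele would be in both genotypes, which argues against it for Cd4. A segment linked to the Cre transgene may hold some of the 12 (p = 0.109, permutation test of 10000 random sets, 1 pair within 1 Mb, insertion site not given in the sources used here). It stays open beside an untested effect of the deletion itself.

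For the effect averaged over tissues edgeR called 0 genes (662 at an unadjusted p under 0.05, and 0 called with the block), with the lowest adjusted p, 0.0854, shared by Dld, Irak2 and 1810053B23Rik. DESeq2 called 22 higher and 16 lower, and DESeq2 with the block 44 and 33.

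Immediate-early and heat-shock genes were higher in islet libraries of both genotypes, and the 7 genes tested here were taken from the calls. RNA of acinar, endocrine or myeloid cells may contribute, since their markers are also higher in islets; the 7 genes summed to 5.53 to 27.3 times those markers, and with no level of the 7 genes in such cells this leaves it open. Digestion of islets at 37 °C may raise such genes, and they exceeded every lymph node library in 8 of 8 islet libraries, but no islet library went without digestion. Digestion and tissue therefore cannot be told apart. A biological difference between tissues stays open and untested.

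For Lag3 deletion in islets, 0 genes passed in the real split of the 8 libraries, so all 35 of 35 splits gave as many and the count carries no information. The highest other split gave 1530 genes, which points to the structure of the samples by number. For lists, 26 of 35 splits gave at least the 2 of the real one, with 14 in the highest other, so chance is not excluded. Of 8 splits that part all 4 pairs, 4 gave as many lists, with at most 4 lists and 0 genes in the others.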
